A study of Biomphalaria glabrata with 16 samples.

How the data were processed

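RNA from the amebocyte-producing organ of the freshwater snail Biomphalaria glabrata was measured on two-colour Agilent arrays. The organ is the part of the anterior pericardial wall that makes the circulating blood cells (hemocytes). Per the labels, adult snails of the schistosome-resistant Salvador strain received 5 µl of phosphate-buffered saline (PBS), lipopolysaccharide (LPS, 1 mg per ml), peptidoglycan (PGN, 1 mg per ml) or fucoidan (FUC, 10 mg per ml). The organs of 20 snails were pooled per sample 24 hours later, and 4 samples were made per group. Each sample was labelled with Cy3 and hybridised against a common reference in Cy5, made per the labels from PBS RNA (80%) and RNA of the 3 treated groups (20%). No array had the dyes exchanged.

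The authors scanned the arrays and extracted the spots with Agilent Feature Extraction. The submitters' notes give version 11.0.1.1, and the headers of the deposited files give version 10.5.1.1. Per the file headers, the deposited spot files hold intensity values per channel (mean spot signal, local background and a processed signal after background subtraction and dye normalisation). They also hold a log ratio, which per the file headers is log10 of red over green, that is reference over sample. The deposited value table is in log10 as well, and it was checked to be this log ratio rounded, with a median of 0 in each of the 16 columns. Its sign was turned and it was put on the log2 scale where it was used as an alternative. All values below were computed from the deposited intensity values and are log2 of Cy3 sample over Cy5 reference.

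Each array holds 62976 spots, of which 1319 are controls. The other 61657 spots carry 30647 probes of 60 bases, with 2 to 3 spots per probe. The files give 1 description for all probes and no probe matched the supplied gene table, so genes could be named only where the probe name itself holds a name. This was so for 96 probes, of which 58 hold Bg, BG or FREP in their names and 38 start with Sm or Ep, prefixes that the files do not explain. A set of 26 keyword lists fixed before the data were examined found no description and 2 probe names, and none of its lists reached the 5 members needed for a test. The lists used in their place (fibrinogen-related proteins, BgFibro, Toll-like receptors, NF-kB, NADPH oxidase, nitric oxide synthase, mitochondrial genes, the BGNS and BGNAS probes of the nuclear ribosomal RNA, and the probes that start with Sm or Ep) were drawn from the probe names after these had been seen and before any comparison was run.

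In R 4.3.3 with limma 3.58.1, background was corrected with normexp and an offset of 50, and loess was applied within each array, with control spots and outlier spots at weight 0. Spots were averaged per probe. A probe was tested if at least 50% of its spots were well above background in Cy3 on all 4 arrays of at least 1 group, which left 14362 probes. The 4 groups were fitted together with lmFit and eBayes. Tests were two-sided, and p values were adjusted by Benjamini and Hochberg within each of the 6 comparisons. A probe is called raised or lowered below where its adjusted p lies under 0.05. Values are log2 fold changes with the standard error of the fit (SE), or group means with the standard deviation between samples (SD).

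FUC 1 and FUC 2 differed by no more than the noise between spots and were counted as 1 sample. The SD of their difference over probes was 0.137 on the log2 scale, against 0.135 expected from the spread between spots of a probe, a variance ratio of 1.03. The other 23 pairs of arrays within groups had ratios of 2.15 to 16.3, and the other FUC pairs 2.85 to 5.15. Their ratios were averaged, which left 15 samples and 3 FUC samples. The plan made before the data were examined had counted 16 samples. The rule that averages such arrays was applied after the data and the results with 16 samples had been seen, and those results are given as an alternative. The labels do not say whether both arrays carried the same pool.

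On each array 11569 to 19877 probes (37.7% to 64.9%) were well above background in Cy3, and no tested probe was saturated in Cy3 on any array. The number of arrays limits the precision: the median SE of a fold change was 0.0989 for groups of 4 samples and 0.107 for comparisons with FUC. The fit was tested on simulated log ratios with independent noise of 1 spread per probe. Changes were added to 200 of the 14362 probes, with 100 changed by 1.5-fold and 100 by 2-fold. Background correction, loess and the filter were not part of this test. Nor were deviations shared between arrays or spreads that differ between groups, so the false calls may be fewer than in the real data. In LPS against PBS, 77 and 98 of these were recovered with 7 false calls. The recovered numbers were 73 and 95 in PGN against PBS, and 74 and 98 in FUC against PBS. Between preparations they were 74 and 97 in LPS against PGN, 83 and 97 in LPS against FUC, and 71 and 90 in FUC against PGN. False calls numbered 13, 10, 12, 15 and 15 in these 5 comparisons.

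Named probes were chosen by a rule fixed before the data were examined. In each comparison with PBS it takes up to 12 raised and 8 lowered probes with an informative name whose treated samples all lie beyond all PBS samples. It takes up to 5 per direction between preparations, up to 3 called members and the 2 brightest uncalled members of each list, and 2 probe IDs per direction. Lists with at least 5 measured probes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which gave 30 list tests.

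The alternatives were no background subtraction, the processed log ratio, the deposited value table, median centring without loess, Aquantile between arrays, Cy3 alone with quantile normalisation, no filter on dim probes, a stricter filter, eBayes with trend and robust options, array weights, a replicate block, a slide or scan block, fits of only the groups compared, a 2-fold minimum, an adjusted p under 0.01, and leaving out each sample in turn. Leaving out both PBS 2 and LPS 2, keeping FUC 1 and FUC 2 apart, and a replicate block for PBS and LPS alone were chosen after seeing the data. The block for PBS and LPS rests on their deviations from the group means, which correlated at over 0.1 in all 4 pairs of arrays with the same number (0.128 to 0.541). These pairs share a row of 1 slide, and the labels name nothing else that they share. In the other 5 comparisons at most 1 of 4 pairs reached this, and the pairs were first judged over all comparisons together. The pairing of PBS and LPS is uncertain, since PBS 1 correlated more with LPS 4 (0.261) and LPS 3 (0.213) than with LPS 1 (0.128). PBS 2, PBS 3 and PBS 4 each correlated best with the LPS array of their own number. For named probes, 12 of these settings could change a value (13 in LPS against PBS, and 1 fewer for probes that the stricter filter removed). They include both the processed log ratio and the deposited value table, which hold the same ratios and are not separate checks. The mean of several probes per gene was not run, because the files do not say which probes share a gene; the 30647 probes have 30563 distinct sequences. Figures were drawn with matplotlib 3.10.9.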

Results

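The data are expression profiles of the amebocyte-producing organ 24 hours after injection, from 16 arrays in 4 groups (PBS, LPS, PGN and FUC, 4 arrays each). LPS is a component of the outer membrane of Gram-negative bacteria, PGN of the bacterial cell wall, and fucoidan is a sulfated, fucose-rich polysaccharide of brown algae. All 3 were crude preparations. The title of the series presents them as patterns that stand for pathogens and asks which genes of the organ respond, among them genes of cell proliferation, immunity and detoxification. FUC 1 and FUC 2 differed by no more than the noise between spots and were counted as 1 sample, so that 15 samples (3 of FUC) were compared. Of 58 probes whose names hold Bg, BG or FREP and a gene, 42 were bright enough to test. They cover immune genes (22 tested of 33), mitochondrial genes (10 of 15) and nuclear ribosomal RNA (10 of 10). Cell proliferation and detoxification could not be examined by name, since no probe name belongs to them.

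The arrays sat on 2 slides, PBS beside LPS on one and FUC beside PGN on the other, with 1 group per column. The scans divide in the same way. LPS against PBS and FUC against PGN were therefore compared within a slide, but between columns. In the other 4 comparisons the slide and the group cannot be told apart, and no fit with the slide as a term could be had. On the first principal component (31.2% of the variance) PBS had a mean of -25.5, LPS 9.92, PGN 12.7 and FUC 2.81. Single arrays weigh on these means. PBS 2 stood at -50.3, against -21.5 to -11.6 on the other PBS arrays. LPS 2 stood at -6.65, against 11.5 to 17.8 on the other LPS arrays. On the second (25.8%) LPS stood at -22.3 and FUC at 21.4. PBS 2 stood apart from the other arrays: its median Cy3 signal over tested probes was 78.1, against 95.7 to 278 elsewhere, and its spike-in ratios had a slope of -0.0909 on their expected values, against 0.710 to 0.796.

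LPS against PBS asks what a Gram-negative surface component changes in the organ. The largest change of a named immune probe was in BgMFREP4_1, named for a fibrinogen-related protein (FREP), a family of snail lectins with a fibrinogen domain that are found in the hemolymph. It was 8.29-fold higher with LPS (log2 3.05 ± 0.38 SE, n = 4 and 4, adjusted p = 6.6e-05), from a mean of -1.79 ± 1.11 (SD) with PBS to 1.26 ± 0.16 with LPS. BgFibro3_2 was 2.46-fold higher (log2 1.30 ± 0.29, adjusted p = 0.0061). BgMFREP5 fell by 0.80 ± 0.17 on the log2 scale (adjusted p = 0.0040). In these probes all 4 LPS samples lay beyond all 4 PBS samples. Of the 9 measured FREP probes, 1 rose, 1 fell and 7 did not pass, both over all probes and adjusted over the list alone. The brightest of those that did not pass were BgMFREP9 (log2 0.20 ± 0.13) and BgMFREP2_1 (log2 0.57 ± 0.42), with 0.05 and -0.02 without PBS 2.

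In the signalling lists, 1 of the 3 measured NF-kB probes passed. NF-kB is a transcription factor family that acts downstream of pathogen receptors. Bg_IPT_NFkB_ACN73461_21sd56333 was 1.23-fold higher with LPS (log2 0.30 ± 0.10, adjusted p = 0.0489), with 3 of 4 LPS samples above all PBS samples, and 2 of the 3 passed when adjusted over the list alone. None of the 3 measured Toll-like receptor probes, whose products recognise microbial patterns, and none of the 6 NADPH oxidase probes, which stand for the enzyme that makes superoxide, passed in limma over all probes. At an unadjusted p under 0.05 these numbers were 1 and 0, and adjusted over the list alone they were 1 and 0. Among the 10 mitochondrial probes BGM_ND5, named for a subunit of respiratory complex I, fell by 0.23 ± 0.06 (log2, adjusted p = 0.0221, all 4 LPS samples below PBS), and the other 9 did not pass. BGM_ND5 was dim, with a mean Cy3 signal of 84.6 where the median background was 32.5 to 42.5. It was above background on all 4 arrays of each group. BGNS_ITS2, on a spacer that is removed from the ribosomal RNA precursor, rose 1.42-fold (log2 0.51 ± 0.11, adjusted p = 0.0045, 4 of 4 samples). The other 4 BGNS probes and all 5 BGNAS probes did not pass, with 0 and 2 of them at an unadjusted p under 0.05 in limma; BGNAS_5_8S had a log2 fold change of -0.41 ± 0.14 (adjusted p = 0.0504), and it passed when adjusted over the list alone and with the PBS and LPS samples paired by number (adjusted p = 0.0015).

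In all, LPS changed 2766 of the 14362 probes (19.3%), 1497 raised and 1269 lowered, with a median absolute log2 fold change of 0.45. Changes of at least 2-fold were mostly increases, with 219 raised and 41 lowered. The files do not pair the remaining probes with names. The largest increases were contig_13013 (27.5-fold, adjusted p = 7.4e-09) and c42297_rc (14.8-fold, adjusted p = 1.3e-08), and the largest decreases were BGC00347 (log2 -3.00 ± 0.30) and c19162 (log2 -2.12 ± 0.26). The call of the NF-kB probe was lost without PBS 1, PBS 2, PBS 3, LPS 1, LPS 2 or LPS 3 (adjusted p up to 0.127) and held in 3 of 13 alternative settings. That of BGM_ND5 was lost without LPS 1 or LPS 4 (adjusted p up to 0.0531) and held in 11 of 13 settings, and that of BGNS_ITS2 held in 9 of 13 (adjusted p up to 0.801). With median centring in place of loess 230 probes passed, among them BgMFREP4_1 but not BgFibro3_2, BgMFREP5, BGM_ND5, the NF-kB probe or BGNS_ITS2, and 1588 passed when only these 2 groups were fitted. The balance of directions turned with the processed log ratio (1135 raised and 1257 lowered) and with Cy3 alone (1290 and 1419).

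**Figure D1:**
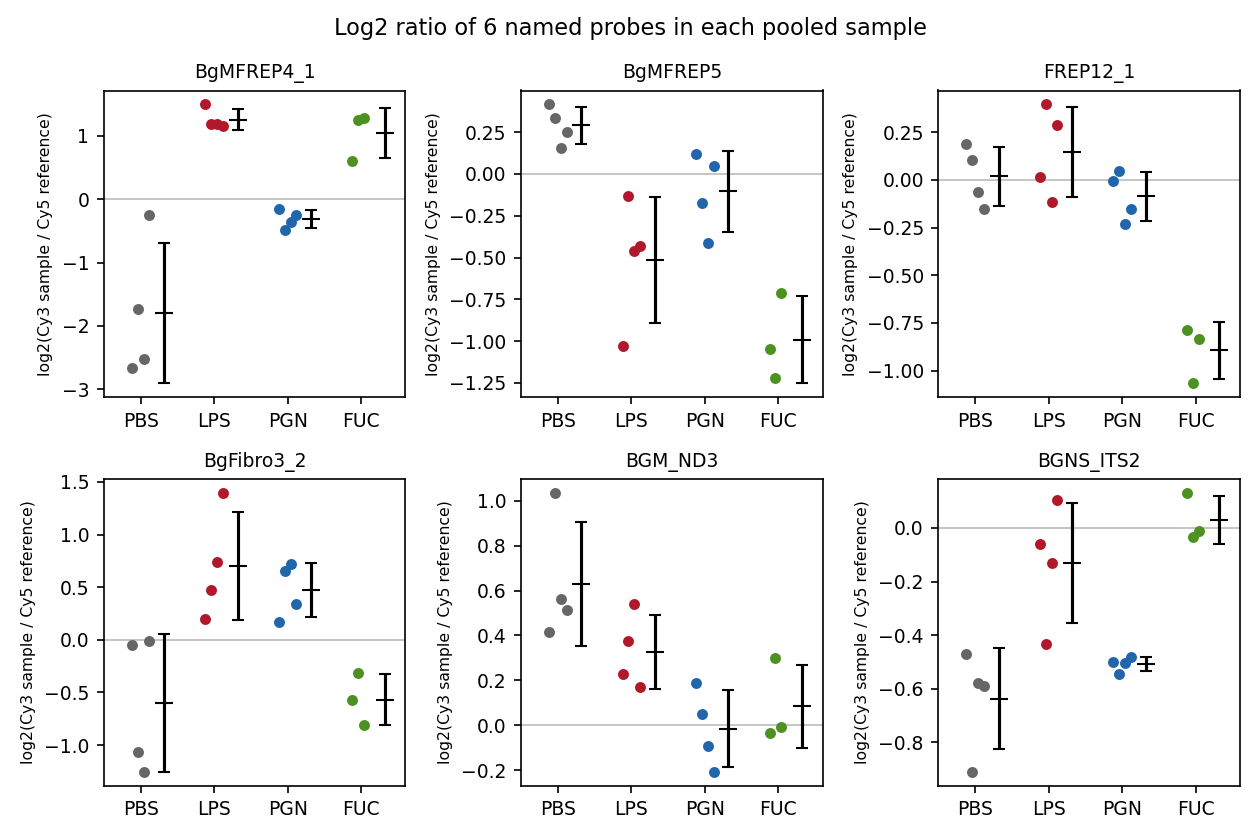
Log2 ratio of Cy3 sample to Cy5 reference (vertical axis) for 6 named probes, in each pooled sample of the 4 groups (points), with the group mean and SD (bars). All LPS and FUC samples of BgMFREP4_1 lie above all PBS samples, and all 3 FUC samples of BgMFREP5 and FREP12_1 lie below all PBS samples; with median centring in place of loess the directions are the same, but the calls of the last 2 are lost.

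PGN against PBS asks what the bacterial cell wall component changes. BgMFREP4_1 was 2.80-fold higher with PGN (log2 1.49 ± 0.38, n = 4 and 4, adjusted p = 0.0156), but only 1 of the 4 PGN samples lay above all PBS samples, because the PBS samples ranged from -2.67 to -0.25. BgFibro3_2 was 2.10-fold higher (log2 1.07 ± 0.29, adjusted p = 0.0209), and BgMFREP9, another FREP, was 1.33-fold higher (log2 0.42 ± 0.13, adjusted p = 0.0362), each in 4 of 4 samples. So 2 of the 9 FREP probes rose, none fell and 7 did not pass, with the same numbers when adjusted over the list alone. BgMFREP2_1 (log2 0.67 ± 0.42, and 0.08 without PBS 2) and BgMFREP6 (log2 -0.18 ± 0.11) were the brightest that did not pass. The NF-kB probe Bg_IPT_NFkB_21sd03877 was 1.25-fold higher (log2 0.32 ± 0.10, adjusted p = 0.0431, 4 of 4 samples), and all 3 NF-kB probes passed when adjusted over the list alone. None of the 3 Toll-like receptor and 6 NADPH oxidase probes passed in limma, with 0 and 1 at an unadjusted p under 0.05 and 0 of each when adjusted over the list alone.

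BGM_ND3, a subunit of respiratory complex I encoded by the mitochondrion, fell by 0.65 ± 0.14 (log2, adjusted p = 0.0052), and the other 9 mitochondrial probes did not pass. Among the ribosomal probes, BGNAS_5_8S fell by 0.73 ± 0.14 (log2, adjusted p = 0.0028), and the other 4 BGNAS probes did not pass. It is the reverse complement of BGNS_5_8S over 29 bases, so these probes read opposite strands. None of the 5 BGNS probes passed, with 2 of those at an unadjusted p under 0.05 in limma. For BGM_ND3 and BGNAS_5_8S all 4 PGN samples lay below all PBS samples. PGN changed 2623 probes (18.3%), 1393 raised and 1230 lowered, and 190 rose and 44 fell by at least 2-fold. More were lowered than raised with the processed log ratio (1038 raised and 1242 lowered) and with Cy3 alone (1263 and 1653). The largest increases were BGC02348 (9.55-fold, adjusted p = 2.8e-06) and c21101 (8.98-fold, adjusted p = 2.0e-06), and the largest decreases BGC00347 (log2 -3.92 ± 0.30) and contig_3633 (log2 -2.61 ± 0.55). In the reference channel, which holds the same RNA on all arrays, 324 probes also differed between these groups, and 2553 of the 2623 called probes were not among them.

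Several of these calls were lost when any of several samples was left out, which also leaves fewer samples for the test. That of BgFibro3_2 was lost without PBS 2, PBS 3, PGN 2 or PGN 3 (adjusted p up to 0.0642), that of BgMFREP9 without PBS 2, PBS 3, PGN 1, PGN 3 or PGN 4 (up to 0.0997), with a log2 fold change of 0.27 without PBS 2, and that of Bg_IPT_NFkB_21sd03877 without any PBS sample or without PGN 1 or PGN 3 (up to 0.122). The number of called probes was 1559 without PGN 3, 1722 with only these 2 groups in the fit, where BgMFREP4_1 had an adjusted p of 0.0602, and 168 with median centring, where BgFibro3_2, BgMFREP9, the NF-kB probe, BGM_ND3 and BGNAS_5_8S did not pass. Over the 12 alternative settings the call of Bg_IPT_NFkB_21sd03877 held in 5, that of BgMFREP9 in 6 and that of BGNAS_5_8S in 10.

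FUC against PBS asks what an algal polysaccharide changes. BgMFREP4_1 was 7.16-fold higher with FUC (log2 2.84 ± 0.41, n = 3 and 4, adjusted p = 4.7e-04), with a mean of 1.05 ± 0.39 (SD). Another 2 FREP probes moved the other way: BgMFREP5 fell by 1.28 ± 0.18 (log2, adjusted p = 4.3e-04) and FREP12_1 fell by 0.91 ± 0.13 (log2, adjusted p = 3.6e-04). All 3 FUC samples lay beyond all PBS samples in these 3 probes, and the other 6 of the 9 FREP probes did not pass; the numbers were the same when adjusted over the list alone. BgFibro3_2, raised by LPS and PGN, had a log2 fold change of 0.03 ± 0.31 with FUC and did not pass. Among the 6 NADPH oxidase probes, Bg_PX_p47phox_21sd01463, named for a cytosolic subunit that activates the enzyme, was 1.17-fold higher (log2 0.23 ± 0.07, adjusted p = 0.0402, 3 of 3 samples), but dim, above background on 3 of 4 arrays in each group. None of the 3 Toll-like receptor probes and none of the 3 NF-kB probes passed in limma, with 0 of each at an unadjusted p under 0.05 and 0 when adjusted over the list alone.

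Among the mitochondrial probes, BGM_COI, the largest subunit of cytochrome c oxidase, was 1.62-fold higher with FUC (log2 0.70 ± 0.17, adjusted p = 0.0119) and BGM_ND3 fell by 0.55 ± 0.15 (log2, adjusted p = 0.0205). The other 8 did not pass; adjusted over the list alone, 4 of all 10 rose and 1 fell, BGM_COI and BGM_ND3 included. Among the ribosomal probes, BGNS_18S (1.82-fold, adjusted p = 0.0254) and BGNS_ITS2 (1.59-fold, adjusted p = 0.0018) rose. So did BGNAS_ITS2 (1.42-fold, adjusted p = 0.0384), which is the reverse complement of BGNS_ITS2 and so reads the other strand. The other 3 BGNS and 4 BGNAS probes did not pass. In each of the mitochondrial and ribosomal probes named here as raised or lowered, all 3 FUC samples lay beyond all PBS samples. FUC changed 2332 probes (16.2%), 1184 raised and 1148 lowered, and 127 rose and 57 fell by at least 2-fold. The largest increases of probes without a gene name were CNX0147 (9.53-fold, adjusted p = 1.1e-04) and contig_6448 (7.05-fold, adjusted p = 0.0192), and the largest decreases c40550 (log2 -2.38 ± 0.38) and c19162 (log2 -2.15 ± 0.28). With the processed log ratio of the scanner software 707 rose and 1120 fell, and with Cy3 alone 968 and 1346. In the reference channel 58 probes differed between FUC and PBS, and 2316 of the 2332 called probes were not among them.

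Calls lost without single samples were those of BGM_COI (FUC 3, adjusted p = 0.0693), BGM_ND3 (FUC 1 and 2 or FUC 4, up to 0.0820), contig_6448 (FUC 3 or FUC 4, up to 0.101; its log2 fold change was 2.82, and 2.02 without PBS 2), Bg_PX_p47phox_21sd01463 (PBS 3, PBS 4 or any FUC sample, up to 0.141), BGNAS_ITS2 (PBS 1, PBS 3, FUC 1 and 2 or FUC 3, up to 0.178) and BGNS_18S (PBS 2 or any FUC sample, up to 0.0875). The number of called probes was 1146 without FUC 3, 1387 without FUC 4 and 1207 with only these 2 groups in the fit. With median centring 13 passed, among them BgMFREP4_1 and CNX0147 but none of the other probes named for FUC. Other settings ended calls as well: that of BGNAS_ITS2 held in 5 of 12 settings, that of Bg_PX_p47phox_21sd01463 in 6 of 11, those of BGNS_18S, BGNS_ITS2 and BGM_ND3 in 9 of 12, and those of BGM_COI and contig_6448 in 10 of 12.

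**Figure D2:**
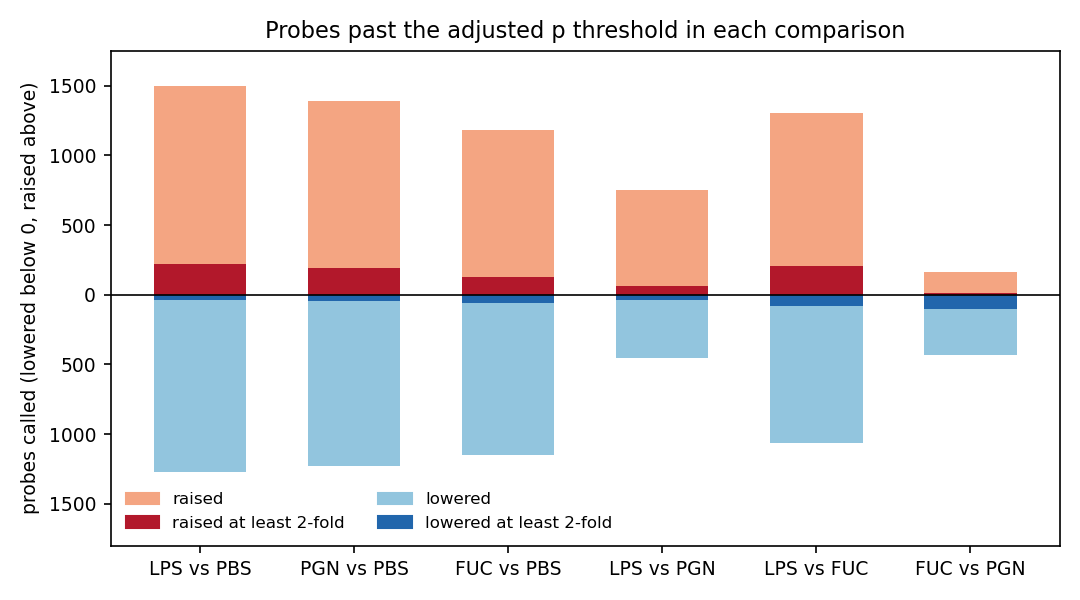
Number of probes called in each comparison (vertical axis, raised above 0 and lowered below 0), with the part that changed at least 2-fold in the darker shade. In this fit of all 4 groups LPS against PBS has the most called probes (2766) and FUC against PGN the fewest (597). With only the groups compared in the fit, LPS against FUC has the most (2464) and FUC against PBS the fewest (1207).

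LPS and PGN, given at the same concentration, were compared directly. BgMFREP4_1 was 2.96-fold higher with LPS than with PGN (log2 1.57 ± 0.38, n = 4 and 4, adjusted p = 0.0201), and BGNS_ITS2 was 1.30-fold higher (log2 0.38 ± 0.11, adjusted p = 0.0445), each in 4 of 4 samples. BgFibro3_2, raised by both against PBS, had a log2 fold change of 0.23 ± 0.29 between them (-0.00395 without LPS 4) and did not pass. The other 8 of the 9 FREP probes did not pass. In the NF-kB (3), Toll-like receptor (3), NADPH oxidase (6) and mitochondrial (10) lists no probe passed in limma, with 0, 1, 0 and 4 at an unadjusted p under 0.05. In all 1201 probes differed (8.36%), 750 higher and 451 lower with LPS. The largest differences were contig_3728 (9.54-fold, adjusted p = 4.6e-07) and c42297_rc (9.01-fold) to the side of LPS, and c11081 (log2 -1.85 ± 0.51, adjusted p = 0.0374) and contig_3665 (log2 -1.85 ± 0.48, adjusted p = 0.0283) to the side of PGN. The last 2 rest mostly on LPS 1 and LPS 3 (-2.23 and -1.58 in c11081, -2.06 and -1.53 in contig_3665). LPS 2 and LPS 4 had 0.34 and 0.24 in c11081, and 0.15 and 0.08 in contig_3665. The PGN samples had 0.75 to 1.30 and 0.75 to 1.31. The processed log ratio put contig_3728, above background on 3 of 4 PGN arrays, at a log2 fold change of 5.40.

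The call of BgMFREP4_1 between LPS and PGN was lost without LPS 1 or PGN 3 (adjusted p up to 0.0580), and that of BGNS_ITS2 without any sample but LPS 2 (up to 0.131). Those of c11081 (any sample but LPS 2 and LPS 4, up to 0.110) and contig_3665 (LPS 1, LPS 3, PGN 1, PGN 3 or PGN 4, up to 0.0885) were lost as well. These fits give a probe 1 spread over all groups, PBS included. For BgMFREP4_1 the SD was 1.11 in PBS, against 0.16 in LPS and 0.14 in PGN. The number of called probes was 782 without LPS 1, 718 without LPS 3, 708 without PGN 1, 686 without PGN 3, 636 with the processed log ratio, 2211 with array weights and 87 with median centring (34 higher and 53 lower with LPS), which put the median of all probes at -0.19 and ended the calls of both genes and of c11081 and contig_3665. Of the 12 alternative settings, the call of BGNS_ITS2 held in 5, that of c11081 in 7 and that of contig_3665 in 8.

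LPS and FUC differed in both the preparation and its concentration. BgFibro3_2 was 2.41-fold higher with LPS than with FUC (log2 1.27 ± 0.31, n = 4 and 3, adjusted p = 0.0129), and FREP12_1 was 2.06-fold higher (log2 1.04 ± 0.13, adjusted p = 6.7e-05). Bg_RHD_NFkB_21sd39482 (1.26-fold, adjusted p = 0.0453) and the Toll-like receptor probe BgTLR_21sd72804 (1.20-fold, adjusted p = 0.0450) were also higher with LPS, but the latter was dim, above background on 2 of the 4 FUC arrays. BGM_COI (log2 -0.60 ± 0.17, adjusted p = 0.0247) and Bg_PX_p47phox_21sd01463 (log2 -0.24 ± 0.07, adjusted p = 0.0337) were lower with LPS than with FUC. In each of these probes all 4 LPS samples lay beyond all 3 FUC samples. Of the lists, 1 of 9 FREP, 1 of 3 NF-kB, 1 of 3 Toll-like receptor, 1 of 6 NADPH oxidase and 1 of 10 mitochondrial probes differed, and all 3 NF-kB probes and 3 mitochondrial probes when adjusted over the list alone. None of the 10 ribosomal probes differed in limma, with 0 at an unadjusted p under 0.05. In all 2367 probes differed (16.5%), 1307 higher and 1060 lower with LPS. The largest differences were contig_13013 (42.6-fold) and contig_1916_rc (log2 4.05 ± 0.27) to the side of LPS, and contig_1623 (log2 -2.23 ± 0.64) and contig_2860_rc (log2 -2.09 ± 0.45, and -2.78 without FUC 1 and 2) to the side of FUC.

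Between LPS and FUC, the call of BgFibro3_2 was lost without FUC 4 (adjusted p = 0.0613) and that of BGM_COI without LPS 2, FUC 3 or FUC 4 (up to 0.117). The calls of Bg_PX_p47phox_21sd01463 (LPS 2, LPS 3 or any FUC sample, up to 0.129), Bg_RHD_NFkB_21sd39482 (any LPS sample, FUC 3 or FUC 4, up to 0.216), BgTLR_21sd72804 (any sample but LPS 2, up to 0.157) and contig_1623 (any sample, up to 0.0914) were lost too. The shared spread of contig_1623 includes PBS 2 at -3.46, against -0.58 to 0.31 in the other PBS samples. Its LPS samples lay at -2.41 to -2.06 and its FUC samples at -0.09 to 0.27. The number of called probes was 1359 without FUC 3, 1507 without FUC 4, 4291 with array weights and 186 with median centring, which ended the calls of all 6 named genes. The call of Bg_RHD_NFkB_21sd39482 held in 4 of 12 alternative settings, those of BgTLR_21sd72804 and Bg_PX_p47phox_21sd01463 in 4 and 7 of 11, and that of contig_1623 in 9 of 12.

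FUC and PGN shared a slide and differed in concentration. BgMFREP5 was lower with FUC than with PGN (log2 -0.89 ± 0.18, n = 3 and 4, adjusted p = 0.0117), and so was FREP12_1 (log2 -0.81 ± 0.13, adjusted p = 0.0016). The mitochondrial probes BGM_CYTB, a subunit of respiratory complex III (1.57-fold, adjusted p = 0.0066), and BGM_ND1, a subunit of complex I (1.42-fold, adjusted p = 0.0225), were higher with FUC, as was BGNS_ITS2 (1.45-fold, adjusted p = 0.0171). In each of these probes all 3 FUC samples lay beyond all 4 PGN samples. Of the 9 FREP probes, 2 were lower with FUC and 7 did not pass, and of all 9, 3 were lower and 1 higher when adjusted over the list alone. BgFibro3_2 had a log2 fold change of -1.04 ± 0.31 and did not pass over all probes (adjusted p = 0.0864). None of the 3 Toll-like receptor, 3 NF-kB and 6 NADPH oxidase probes passed in limma, with 0, 3 and 0 at an unadjusted p under 0.05, and all 3 NF-kB probes were lower with FUC when adjusted over the list alone. In all 597 probes differed (4.16%), 165 higher and 432 lower with FUC, and of those at least 2-fold apart 9 were higher and 100 lower. The largest differences were BGC00347 (log2 2.02 ± 0.33) and contig_6320_rc (log2 1.54 ± 0.23) to the side of FUC, and contig_1916_rc (log2 -4.01 ± 0.27) and contig_13013 (log2 -3.09 ± 0.25) to the side of PGN.

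Between FUC and PGN, the call of BgMFREP5 was lost without FUC 1 and 2 or FUC 3 (adjusted p up to 0.0870), that of BGM_ND1 without FUC 3, FUC 4, PGN 1 or PGN 3 (up to 0.113) and that of BGNS_ITS2 without any FUC sample (up to 0.0818). The number of called probes was 389 without FUC 1 and 2, 255 without FUC 3, 356 without FUC 4, 393 without PGN 1 and 370 without PGN 3. It was 391 (64 higher and 327 lower with FUC) with the processed log ratio, 1549 (593 and 956) with array weights, 1350 with only these 2 groups in the fit and 81 with median centring, which ended the calls of all 5 named genes and of BGC00347 and contig_6320_rc. The calls of BGNS_ITS2 and BGM_ND1 held in 8 and 9 of 12 alternative settings.

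The probes raised or lowered by different preparations were partly the same ones. LPS and PGN raised 692 probes in common and lowered 702, where independent lists of these sizes would share 145.2 and 108.7. PGN and FUC shared 633 raised and 659 lowered probes (114.8 and 98.3 expected), and LPS and FUC shared 376 and 510 (123.4 and 101.4 expected). All 3 preparations raised 307 probes and lowered 409 of the 4780 probes called in at least 1 of them, and 85 probes were called in opposite directions by different preparations. BgMFREP4_1 was raised by all 3, BGM_ND3 was lowered by PGN and FUC, and BgMFREP5 by LPS and FUC. The 3 comparisons share their PBS samples, which adds overlap of its own. With the PBS samples divided 2 and 2, so that no sample was shared, the median overlaps over 6 divisions were 330.5 and 301 for LPS and PGN, 217.5 and 286.5 for PGN and FUC, and 152 and 279 for LPS and FUC. In every division they were over the number expected of independent lists of those sizes, by 1.51 to 7.88 times. A shift common to all PBS arrays, which fill 1 column of 1 slide, stays in both parts. A planned simulation set unchanged groups against the shared PBS samples (50 draws). Its highest correlations of fold changes were 0.824 for LPS and PGN, 0.862 for PGN and FUC, and 0.769 for LPS and FUC. The real ones were lower (0.722, 0.701 and 0.418). Summarised over the draws, the simulated correlations were 0.459, 0.461 and 0.472. For LPS and FUC the real correlation was thus under this value too. The real covariances (0.0888, 0.0798 and 0.0505) were above the simulated ones summarised over the draws (0.0102, 0.0113 and 0.0113). The highest simulated covariance was not recorded, so the real ones cannot be set against every draw.

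Among the preparations, LPS had the most probes that set it apart from each of the other 3 groups, with 409 higher and 104 lower than in every other group. FUC had 60 and 143 such probes, and PGN had 50 and 9. PBS had 409 and 307, the probes that all 3 preparations lowered and raised. FREP12_1 was lower in FUC than in each other group. Some called probes were well above background on all 4 arrays of 1 group and on no array of the other. LPS had 17 such probes against PBS, 31 against FUC and 2 against PGN, PGN had 5 against FUC, 2 against PBS and 1 against LPS, and PBS had 2 against LPS and 2 against FUC. The set of tested probes may favour LPS in such counts, since 14030 of the 14362 were well above background on all 4 LPS arrays, against 11975 for PBS, 11804 for PGN and 11104 for FUC.

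Of the 30 list tests, 1 passed: the mitochondrial probes as a group were higher with FUC than with PGN (camera, median log2 0.35 over 10 probes, adjusted p = 5.1e-04). With an estimated correlation between probes the adjusted p = 0.794, and with fry, which asks whether the probes move one way on balance, the adjusted p = 0.104. The FREP probes passed in all 6 comparisons of the test that asks whether they change in either direction (fry, mixed), with adjusted p from 5.7e-05 in FUC against PBS to 0.0180 in LPS against PGN. The mitochondrial probes passed it in 4, with adjusted p = 0.0434 in PGN against PBS, 0.0120 in FUC against PBS, 0.0367 in LPS against FUC and 0.0068 in FUC against PGN, and the other 3 lists passed it in none. This test does not set a list against other probes, so a few strongly changed members can carry it. In LPS, PGN and FUC against PBS 22.2%, 22.2% and 33.3% of the FREP probes were called, against 19.3%, 18.3% and 16.2% of all probes. In LPS against PGN, LPS against FUC and FUC against PGN these were 11.1%, 11.1% and 22.2%, against 8.36%, 16.5% and 4.16%. In FUC against PBS the FREP list had a mean log2 fold change of 0.19, a median of -0.04 and a camera direction of down. In LPS against PGN its median was -0.02 and its mean 0.00, with a camera direction of up. The mitochondrial list in LPS against PBS had a median of 0.08 and a mean of 0.02, with a camera direction of down. These lists were made from probe names and hold few members.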

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

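Tests chosen only after their results had been seen were those of the position on the slide and of a wrong label, the divisions of the 7 samples in the 3 comparisons with FUC, which had first been run on 8 arrays, and the divisions that keep the pairs of PBS and LPS samples parted.

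In 7 of the 126 groups of 4 values examined, 1 sample lay farther from its nearest neighbour than the 95% limit of Dixon's gap test, where chance alone gives 6.3. Groups of 3 FUC samples were not examined. In BGNAS_ITS2, PBS 1 had a log2 ratio of 0.30 against 0.69 to 0.73 in the other PBS samples, and LPS 1 had 1.41 against 0.77 to 0.88 in the other LPS samples. In BgMFREP4_1, LPS 1 had 1.497 against 1.16 to 1.19. In c21101, PBS 2 had -1.79 against -0.91 to -0.75, and in contig_1623, LPS 2 had -2.41 against -2.12 to -2.06. The median Cy3 signal of tested probes was 95.7 on LPS 2 against 145 to 155 on the other LPS arrays. The slope of the spike-in ratios on their expected values was -0.0909 on PBS 2 against 0.710 to 0.796 on the other PBS arrays.

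PBS 2 also had the lowest spike-in signal (a highest mean of 1278 in Cy3 against 11700 to 29585 on the other arrays) and the widest deviations from its group (SD 0.302). A position that acts alike on both slides is argued against, since deviations of the 3 other arrays of that position correlated with its own at -0.00379 in the lowest case, but a cause shared with LPS 2, beside it on the same slide, stays open (0.541). A wrong label is argued against too, since PBS 2 lay 1.30 times as far from the nearest other group mean as from the mean of the other 3 PBS arrays. A fault of hybridisation or scanning that acts on both channels may have a part: in the reference channel, which holds the same RNA on all arrays, its deviations had an SD of 0.103, the highest of the 16 arrays (next 0.0867). The other PBS arrays were high there too, at 0.0854 to 0.0867, against 0.0524 to 0.0832 in the other groups. The spike-in signal of PBS 2 was low mostly in Cy3: its highest mean in Cy5 was 13592.5, against 14629 to 22505 on the other arrays. Faults of the Cy3 labelling or of the spike-in step were not tested and stay open. No biological explanation was tested, because the design gives none.

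For each comparison the samples were divided in every other way into groups of the same sizes, 35 divisions with the real one. In LPS against PBS only 1 division, the real one, called as many as 2766 probes, and the highest of the others called 1665, with PBS 1 and LPS 2 exchanged. Since these samples may pair by number, the 8 divisions that part all 4 pairs were compared too. The highest other called 0, and with the pairs as a block 19 against 3827, but 8 divisions are too few for a share under 0.05. In PGN against PBS only 1 called as many as 2623, and the highest other called 1. In FUC against PBS only 1 called as many as 2332, and the highest other called 1600, with PBS 1 put with the FUC samples. In LPS against PGN only 1 called as many as 1201, and the highest other called 0. In LPS against FUC only 1 called as many as 2367, and the highest other called 832, with LPS 2 put with the FUC samples. In FUC against PGN only 1 called as many as 597, and the highest other called 36. In each of the 6 comparisons the real division called the most probes of the 35. For each comparison taken alone, this argues against chance as the source of the number of calls. It cannot exclude chance over the 6 together, since 35 divisions limit how small the share can be. Nor can it do so in LPS against PBS if the samples pair by number. It does not bear on any single call.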

How the results depend on the processing

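Leaving out both PBS 2 and LPS 2, keeping FUC 1 and FUC 2 as separate samples, and the replicate block for PBS and LPS alone were chosen after seeing the data. The other settings were fixed before, but they were run again with FUC 1 and FUC 2 averaged after the results with 16 samples had been seen. Counts are given in the order LPS, PGN and FUC against PBS, LPS against PGN, LPS against FUC, and FUC against PGN, where the settings of the report gave 2766, 2623, 2332, 1201, 2367 and 597. No named value that passed changed its direction in any setting. Without background subtraction, with Cy3 alone, without the filter on dim probes, with the stricter filter, and with trend and robust options, all 6 counts stayed within 1.5 times.

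Median centring without loess gave 230, 168, 13, 87, 186 and 81 (153, 152, 9, 34, 146 and 1 raised). The median residual SD was then 0.302 against 0.141 with loess, 2.14 times as wide. Fitting only the groups compared gave 1588, 1722, 1207, 1361, 2464 and 1350, so that LPS against FUC then had the most. The counts against PBS fell and those between preparations rose. Deviations from the group mean had a mean SD of 0.217 on PBS arrays, 0.172 on LPS, 0.131 on PGN and 0.132 on FUC arrays. The fit of all 4 groups gives each probe 1 spread. Whether this made the counts shift was not tested. Asking for at least 2-fold gave 260, 234, 184, 104, 287 and 109, and an adjusted p under 0.01 gave 1429, 1043, 995, 456, 1126 and 268; both are stricter by construction. The processed log ratio and the deposited value table, which holds these ratios rounded, each gave 636 for LPS against PGN and 391 for FUC against PGN. Array weights gave 2211, 4291 and 1549 in the last 3 comparisons. Without PBS 2 and LPS 2, 1006 passed in FUC against PGN. Beyond the wider spread with median centring and the 2 stricter thresholds, the cause was not tested.

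Leaving out 1 sample gave 2006 to 3343, 1559 to 3211, 1146 to 2814, 686 to 1137, 1359 to 2255 and 255 to 466; the cause was not tested. Keeping FUC 1 and FUC 2 apart gave 2919, 2763, 3090, 1293, 2966 and 892. In LPS against PBS all 4 pairs of arrays with the same number had deviations that correlated at over 0.1, which was not so in the other 5 comparisons. The pairing is uncertain, since PBS 1 correlated more with LPS 4 (0.261) than with LPS 1 (0.128). Of the 16 arrays, 4 correlated best with one of their own number. With these 4 pairs as a block 3827 probes passed in LPS against PBS (2192 raised), and among named values the block added the call of BGNAS_5_8S and changed no other; of the list tests 1 passed. With the replicate number as a block in all groups the counts were 3046, 3139, 2091, 1335, 2282 and 643. A slide or scan block could not be fitted for 4 comparisons and changes nothing by construction in LPS against PBS (2766) and FUC against PGN (597). Aquantile leaves the ratios unchanged by construction, and the mean of several probes per gene was not run.

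The overlaps of LPS and PGN, LPS and FUC, and PGN and FUC (raised, then lowered) were 291 and 278, 110 and 218, and 193 and 237 at an adjusted p under 0.01. With the PBS samples divided they were 330.5 and 301, 152 and 279, and 217.5 and 286.5, with fewer PBS samples in each comparison. Of the list tests 1 passed, with or without any 1 sample, and 0 passed with an estimated correlation, with fry or with median centring (adjusted p = 0.794, 0.104 and 0.188 for the mitochondrial probes in FUC against PGN); the cause was not tested.

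Of the 58 named values that passed, 19 still passed with median centring, 44 with the processed log ratio, 45 with Cy3 alone, 48 without the filter, 48 with only the groups compared, 50 with the replicate block, 53 without background subtraction, 55 with trend and robust options, 56 with array weights and 57 with FUC 1 and FUC 2 apart. All 54 that the stricter filter kept passed. Over all fits without 1 sample, 334 of 432 passed. Signal limits what can be seen: 14362 of 30647 probes were bright enough to test, and 16 of the 58 probes with a gene in their name were not.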

Other observations

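Of the tests in this part, those that leave out samples or regroup them for the correlation in the last paragraph were chosen after that correlation had been seen, a regrouping equal to the real grouping was removed after a first run, and all tests were run again with FUC 1 and FUC 2 averaged after the results with 16 arrays had been seen.

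Among the probes with large changes, 2 were picked after their values had been seen because LPS and PGN raised them and FUC did not. The probe c21101 was higher with LPS (log2 3.41) and with PGN (log2 3.17) than with PBS, and had a log2 fold change of 0.42 with FUC (adjusted p = 0.294). The probe contig_1916_rc rose with LPS (log2 2.86) and PGN (log2 2.82) and fell with FUC (log2 -1.20, adjusted p = 0.00879). Compared directly, both were higher with LPS than with FUC (log2 2.99 and 4.05) and lower with FUC than with PGN (log2 -2.75 and -4.01). The files pair neither with a gene.

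The BGNS and BGNAS probes of ITS2 are reverse complements over 60 bases, those of ITS1 over 54 and those of 5.8S over 29; those of 18S and 28S share no run of 14 bases or more. Of the 26 probes that start with Sm, 14 were above background on no array and 2 on all 16, and of the 12 that start with Ep, 4 were on none and 1 on all 16. Sm_5_8S and Ep_5_8S share a run of 24 bases with BGNS_5_8S. None of the 2 Sm and 3 Ep probes tested was called in limma in any of the 6 comparisons, over all probes or over the list alone, with 1 Sm probe at an unadjusted p under 0.05 in PGN against PBS and 0 elsewhere. The nitric oxide synthase probe was too dim to test, and so was 1 of the 2 BgFibro probes.

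PGN and FUC changed many of the same probes against PBS, which sat on the other slide from both, so a difference between the slides could have made the overlap. Probes called in PGN and FUC against PBS 1 and PBS 2 were followed in LPS against PBS 3 and PBS 4, which share a slide. Of these, 81.2% moved the same way (71.2% to 95.4% over the 6 ways to divide the PBS samples), 28.4% were called the same way (17.7% to 72.5%), and the median change was 0.24 in LPS against 0.61 in PGN and FUC (log2), which argues against the slide as the whole cause, for which a share of at most 55% had been set. A part from the slide stays open, since 324 probes differed between PGN and PBS and 58 between FUC and PBS in the reference channel. The smaller change in LPS cannot decide this, because the probes had been chosen by their changes in PGN and FUC. A response common to the 3 preparations is a hypothesis that stays open as well.

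LPS minus PBS and PGN minus FUC share no array and no slide, yet they correlated across probes (r = 0.406, Spearman 0.198; 0.378 without PBS 4 to 0.412 over the samples left out in turn), with 222 probes raised in both (independent lists would share 45.0) and 59 lowered in both (14.6), but 69 moved opposite ways and only 56.0% of all probes had the same sign. Over 100 regroupings within the slides the median absolute r was 0.1002 and the highest 0.402, so the real grouping was above all of these, but narrowly above the highest. GC content and signal of the probes are argued against, since r was 0.404 after their trend had been removed. The column on the slide may have a part, because LPS and PGN sat in 1 column and PBS and FUC in the other: in the reference channel the same 2 differences correlated at 0.151, between the bounds set for the test. The column and a response common to the 2 bacterial preparations cannot be told apart, because each group fills 1 column of 1 slide.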
